A study of Arabidopsis thaliana with 24 samples.

How the data were processed

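RNA from roots of hydroponically grown Arabidopsis thaliana was measured on 24 one-colour Affymetrix arrays, 3 in each of 8 groups formed by the time after transfer (0, 1, 6 and 24 h) and by the Pi supply (none, or 1.5 mM). Per the labels' protocols, 30-day-old plants grew in a cycle of 10 h light and 14 h dark at 21 and 18 °C, their roots were washed briefly with EDTA, and the transfer began 1 h into the light period. About 20 plants were used per time, the roots went into an RNA preservative, and biotin-labelled cRNA was made with a one-cycle kit. The labels number the experiment 1 to 3, and this number was taken as the replicate.

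The values of each array are on a log2 scale in the authors' deposited value table, with a range of 2.61 to 14.2. How the authors summarised probes and normalized the arrays is not given in the sources used here. Per the submitters' processing notes limma was used, with no version named. The authors' deposited comparison table holds log2 fold changes, test statistics (a score with no fixed range, per the file headers) and p-values for minus Pi against plus Pi at each time. No column of per-sample values was left unused.

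The value table had 22810 probe sets. The 64 Affymetrix control probe sets were left out, which left 22746. A probe set's gene was taken from the locus column of the authors' deposited table, filled for 9999 probe sets, and otherwise from GEO's platform annotation, which can be old. In this way 17103 probe sets named 1 gene (9395 from the deposited column, 7708 from the platform annotation), 672 named several and 4971 were unnamed here, for 16928 genes in all. Where both sources named a gene, 5575 of 5596 probe sets had the same locus. Symbols came from NCBI's gene table for the TAIR10.1 assembly, and no coordinates were used. Genes were named only from probe sets with 1 gene.

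All tests used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. A linear model with a mean for each of the 8 groups was fitted to all 24 arrays, with 16 residual degrees of freedom, followed by empirical Bayes moderation. The contrasts were minus Pi against plus Pi at the 4 times, 1, 6 and 24 h against 0 h in plus Pi roots, and 4 differences of the Pi effect between times. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets within each contrast, with a threshold of 0.05. The smallest p that 3 arrays against 3 allow by exact permutation does not reach that threshold, so the calls rest on the spread pooled over groups and genes.

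The experiment number marks a run of the whole experiment in the labels, so it pairs the arrays. Deviations from the group means correlated with a mean r of 0.554 between arrays of one experiment (0.0984 to 0.836) and -0.261 between experiments (-0.805 to 0.587). Deviations within a group cancel out, so the negative mean between experiments largely follows from the positive one and is no separate support. The lowest r among the 12 pairs compared at one time was 0.228, and 22 of 24 arrays correlated best with an array of their own experiment. The fit with the experiment as a fixed block had 14 residual degrees of freedom and its value stands beside each count of calls, over all probe sets or in a list, that it moved by over 1.5 times. As a random block the experiment had a correlation of 0.384. Replicate arrays correlated with r between 0.9503 and 0.992, and 0 pairs of arrays were identical.

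Before the data were examined, 23 gene lists with 365 genes were fixed by locus, for Pi, iron, nitrogen and sulfur nutrition, hormones, stress, the clock and the cell types that root samples or stray leaf tissue could hold. A list gene was represented by the probe set with the highest mean among those naming only that gene, and 176 genes were measured. The 21 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted by Benjamini-Hochberg over the lists within each contrast. With the preset correlation 40 of 147 list tests passed, with an estimated correlation 12. Member counts are given over all probe sets and adjusted over the list alone.

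The genes named in the text followed a rule fixed before the data were examined. For each Pi effect it took the 12 largest positive and the 12 largest negative differences among called probe sets with 1 gene and the same sign in the 3 experiments, and at 0 h, where none was called, the 3 smallest p-values. For each time effect it took the 5 largest rises and falls, and for each difference of Pi effects the 5 smallest adjusted p. Up to 4 passing members per list, and a set of fixed markers, could be named at any time. Of these markers only SPX1, IRT1, FER1 and TOC1 had a probe set naming 1 gene. The others, among them SPX3, PAP17, MGD3, CCA1 and LHY, had none and could not be followed. Genes named after their values were seen are marked as such.

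The fit was tested on simulated data for the Pi effect at 6 h, on 22746 probe sets, each drawn around its mean over all arrays with its residual spread, with 200 of them changed and no differences between experiments built in. Without the block it recovered 44.8% of 67 probe sets changed 1.5-fold, 77.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 11 wrong calls. With the block it recovered 37.3%, 74.6% and 95.5%, with 9 wrong calls.

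The alternatives fixed beforehand were a 2-fold minimum, only the arrays compared, the fixed and random block, an intensity trend and robust moderation, quantile normalization and median centring of the deposited values, a filter on the 40% dimmest probe sets, one probe set per gene, the mean over a gene's probe sets for the lists, and each experiment and each array left out in turn. Also fixed were fits without 3 arrays of experiment 2 whose scan numbers in the labels lay outside that experiment's run (1 h plus Pi, 6 h minus Pi and 24 h minus Pi), and without 2 arrays of experiment 3 whose names mark a second scan (1 h and 6 h minus Pi). Floors at 16, 32 and 64 were applied to the Pi effects after undoing the log. For the random block and robust moderation, lists were tested with limma's cameraPR on the moderated statistics. Fits without the 0 h pair of experiment 2, and without each experiment together with the block, were added after seeing the data.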

Results

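The data were 24 arrays of root RNA from Arabidopsis thaliana plants grown in nutrient solution. At 30 days of age the plants were moved to solution without phosphate (Pi) or with 1.5 mM Pi, and roots were taken directly (0 h) or after 1, 6 or 24 h. This gave 8 groups of 3 arrays; the experiment was run 3 times and each run gave 1 array per group. Roots without Pi are called minus Pi roots and roots kept with Pi are called plus Pi roots. The array was an Affymetrix chip whose probe sets each report the transcripts of a gene or of several similar genes. Of 22746 probe sets tested, 17103 named 1 gene, 672 named several genes and 4971 were unnamed here, so that 176 of the 365 genes of the fixed gene lists were measured under a name. The array medians lay between 6.345 and 6.454 on the log2 scale. The first principal component held 37.6% of the variance, of which 80% lay between the 3 experiments. The number of arrays per group limits the precision. The Pi effect at a time is minus Pi less plus Pi roots at that time, so a gene called higher or lower differed between both arms and need not have changed from its own 0 h level. Values are log2 differences from the limma fit over all 24 arrays, with their standard error (SE), and adjusted p-values are Benjamini-Hochberg values.

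The comparison at 0 h, when no Pi had been withheld for any time, served as the background of the later ones. The named genes with the smallest p were AT1G61890, 0.68 higher in minus Pi roots (SE 0.168), RRTF1, a redox-responsive transcription factor gene, 1.01 higher (SE 0.262), and AT2G32030, 0.65 higher (SE 0.172). Each was higher in 3 of 3 experiments, with a limma adjusted p = 1. SPX1, a gene of Pi sensing, differed by -0.40 (SE 0.357) and the root iron transporter gene IRT1 by -1.29 (SE 1.08), both at adjusted p = 1. No probe set passed the threshold in limma, with the experiment as a fixed or a random block either. Of 22746 probe sets 301 had an unadjusted p under 0.05 (920 with the fixed block). Both are smaller shares than the 0.05 that chance alone would give on average. The fit without the block keeps differences between experiments in its residual spread, so its SE can be larger than in a paired fit.

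No list had a member past the threshold at 0 h, and over the list alone 1 of 12 root hair genes was higher. The root hair list had a median of 0.80 and passed camera with its preset correlation (adjusted p = 7.45e-09), but not with an estimated correlation (adjusted p = 0.166). Its medians in experiments 1 to 3 were 0.33, 1.39 and 0.84. The touch and rapid stress list (median 0.37, adjusted p = 1.76e-05), the iron acquisition list (median -0.16, adjusted p = 0.0137) and the sulfate list (median -0.47, adjusted p = 0.0137) passed likewise. With an estimated correlation these 3 gave adjusted p = 0.237, 0.604 and 0.311. In experiments 1 to 3 the medians were 0.57, 0.17 and 0.425 for the touch list, -0.128, -0.626 and 0.201 for the iron acquisition list and -0.331, 0.0166 and -0.876 for the sulfate list. Without experiment 2 the iron acquisition list changed its sign, to a median of 0.0391 (adjusted p = 0.93).

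After 1 h, TCH4 (AT5G57560), a touch-inducible xyloglucan-modifying enzyme of the cell wall, was 5.16 higher without Pi (SE 0.436, adjusted p = 1.23e-05), which is 35.6-fold, at 11.99 ± 0.0133 against 6.83 ± 0.163 in plus Pi roots (SD, n = 3; limma). At 0 h its level in minus Pi roots was 10.40 ± 0.525. PHI-1 (AT1G35140) was higher by 4.73 (SE 0.538), the expansin-like gene EXLA2 by 3.21 (SE 0.352), the mitochondrial dicarboxylate carrier gene DIC2 by 2.58 (SE 0.342), the transcription factor gene WRKY18 by 2.51 (SE 0.252) and EXO by 2.47 (SE 0.239). DIC2 stood at 9.16 in minus Pi roots at 1 h, against 9.88 in plus Pi roots at 0 h and 6.58 in plus Pi roots at 1 h. AT5G52760 and sks9 were higher by 3.79 (SE 0.708) and 3.44 (SE 0.335), and AT1G56060, AT1G76640, AT3G55840 and AT2G41640 by 2.54 to 2.82. Of the genes that were lower, the expansin gene EXPA9 differed by -2.05 (SE 0.321), GASA4, a gibberellin-responsive gene, differed by -0.98 (SE 0.219) and HA8, a plasma membrane proton pump gene, differed by -0.85 (SE 0.145). AT4G31320 differed by -2.12, AT2G36690 differed by -2.07 and AT1G36060 differed by -1.42, and the transcription factor genes MYB40 and GATA12 differed by -1.14 and -0.80. AT3G24670, AT5G40630, iqd33 and EXO70H1 differed by -1.20, -1.05, -0.94 and -0.90. The rule that chose these genes required the same sign in 3 of 3 experiments.

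Of 12 measured touch and rapid stress genes, 3 were higher in minus Pi than in plus Pi roots at 1 h over all probe sets (TCH4, WRKY18 and TCH2, a calmodulin-like gene, by 1.92 with SE 0.179). With the experiment as a block 6 were, and 6 adjusted over the list alone. TCH2 stood at 9.18 in minus Pi roots at 1 h, against 9.19 in plus Pi roots at 0 h and 7.26 in plus Pi roots at 1 h. The list median was 1.25 (camera adjusted p = 1.2e-12; adjusted p = 0.0234 with an estimated correlation, and adjusted p = 0.191 with that correlation and the experiment as a block). Its medians in experiments 1 to 3 were 1.42, 1.31 and 0.94. Within minus Pi roots the median of the same list changed from 0 h to 1 h by -1.16, -0.25 and -0.59 in the 3 experiments. Of 9 ethylene genes, EIN2, a central component of ethylene signalling, differed by -0.58 (SE 0.0953, adjusted p = 0.00273), and over the list alone 2 were higher and 3 lower (1 and 1 over all probe sets with the block). That list had a median of -0.11, a mean of 0.11 and a camera adjusted p = 0.537.

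None of 14 measured phosphate sensing and transport genes, 7 phosphate scavenging genes or 6 membrane lipid genes passed the threshold at 1 h, over all probe sets or over the list alone, and SPX1 differed by 0.22 (SE 0.357, adjusted p = 0.954). Other fixed members of these lists, such as SPX3, PAP17 and MGD3, had no probe set naming only that gene, so these counts do not cover them. The heat shock list (median 0.47, adjusted p = 0.00862, with 1 of 10 genes higher over the list alone) and the root hair list (median -0.54, adjusted p = 0.0462) passed camera. With an estimated correlation they gave adjusted p = 0.491 and 0.757. No gene of the remaining lists passed at 1 h over all probe sets or over the list alone. The phosphate sensing and transport list had a median of 0.02 and a mean of 0.07 where camera's direction was down (adjusted p = 0.95). With the block 1 heat shock gene was higher and 1 root hair gene lower.

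In all, 258 probe sets differed at 1 h by limma, 161 higher and 97 lower in minus Pi roots, and 902 did (438 higher, 464 lower) with the experiment as a block. After median centring of the arrays the split was 190 higher and 50 lower. The count was 108 at 2-fold or more, 70 with only the 6 arrays compared and 106 without the 3 arrays numbered out of run. It was 155 without the minus Pi array of experiment 1, 142 and 141 without the minus Pi and the plus Pi array of experiment 2, and 130, 12 and 89 without experiments 1, 2 and 3.

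At 6 h, ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, was 4.12 higher without Pi (SE 0.232, adjusted p = 4.26e-09) at 8.85 ± 0.297 against 4.73 ± 0.259 (SD, n = 3; limma). ASN1, an asparagine synthetase gene, was higher by 3.44 (SE 0.772), PPDK, a pyruvate phosphate dikinase gene, by 3.43 (SE 0.71), the nitrilase gene NIT4 by 3.67 (SE 0.555) and the sugar transporter gene MSS1 by 3.65 (SE 0.502). PGIP1, an inhibitor of pectin-degrading enzymes, was higher by 4.46 (SE 0.676), the glutathione transferase gene GSTU25 by 3.34 (SE 0.567) and the defensin-like gene LCR67 by 3.96 (SE 0.657). AT3G60420, AT2G41380 and AT5G39580 were higher by 4.71 (SE 0.604), 4.50 (SE 0.231) and 3.61 (SE 0.603), and TCH4 was 3.89 higher (SE 0.436). Among the genes that were lower, AGP13 and AGP22, which encode arabinogalactan proteins of the cell surface, differed by -3.72 (SE 0.368) and -3.27 (SE 0.397). The wall enzyme genes XTH21 and XTH16 differed by -2.71 (SE 0.325) and -2.71 (SE 0.475), and the tubulin gene TUB1 differed by -2.72 (SE 0.374). AT1G09750 differed by -3.96 (SE 0.412), and sks15, ARP1, AT3G59370, AT4G22460, AT4G25250 and AT3G18450 differed by between -2.96 and -2.42. The rule that chose these genes required the same sign in 3 of 3 experiments.

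Of 14 phosphate sensing and transport genes, 5 were higher at 6 h (7 adjusted over the list alone) and none was lower. SPX1 was higher by 1.63 (SE 0.357, adjusted p = 0.0074), the transcription factor gene WRKY6 by 1.63 (SE 0.39), and LPR1 and LPR2, which act in the root growth response to low Pi, by 1.33 (SE 0.18) and 0.98 (SE 0.184). The remaining one, PHR1, a transcription factor gene of the Pi starvation response named after its value was seen, was higher by 0.46 (SE 0.0934, adjusted p = 0.00469). The list median was 0.71 (camera adjusted p = 0.000194; adjusted p = 0.0253 with an estimated correlation). Of 9 ethylene genes 4 were higher (5 over the list alone): ERF2 by 2.02 (SE 0.464), the ethylene synthesis gene ACS7 by 1.05 (SE 0.278), the kinase gene CTR1 by 0.71 (SE 0.122) and the receptor gene ERS1 by 0.59 (SE 0.16). CTR1 and ERS1 are known as negative regulators of the ethylene response. The ethylene list had a median of 0.59 and passed at adjusted p = 0.00265, at adjusted p = 0.0253 with an estimated correlation, and not with that correlation and the block (adjusted p = 0.162).

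The ferritin gene FER1, which encodes an iron store, was higher by 2.06 at 6 h (SE 0.317, adjusted p = 0.000551), 1 of 3 iron storage genes, and PYE was higher by 0.78 (SE 0.143), 1 of 13 iron acquisition genes (2 higher and 1 lower with the block), while IRT1 differed by 0.24 (SE 1.08, adjusted p = 0.953). Of 9 genes of glycolytic bypass and respiration, 2 were higher (PPDK, and NDB2 by 1.23 with SE 0.351) and 3 lower, all of them phosphofructokinase subunit genes of the pyrophosphate-dependent kind: AT1G20950 differed by -0.86 (SE 0.148), AT1G12000 differed by -0.61 (SE 0.152) and AT1G76550, named after its value was seen, differed by -0.53 (SE 0.113). That list had a median of -0.14 and a mean of 0.24 (camera adjusted p = 0.392). NRT1.8, a nitrate transporter gene, was higher by 2.1 (SE 0.513) beside ASN1, 2 of 11 nitrate and ammonium genes (median -0.04, mean 0.36, adjusted p = 0.465). The sulfate transporter gene SULTR4;1 was higher by 0.65 (SE 0.173), 1 of 8 sulfate genes, and PAH2 and MGD1 were higher by 0.54 (SE 0.162) and 0.43 (SE 0.126), 2 of 6 membrane lipid genes. None of the 7 measured phosphate scavenging genes passed, and PAP17 was not among them.

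In the touch and rapid stress list 3 of 12 were higher at 6 h (4 over the list alone), with RHL41 2.25 higher (SE 0.456) and WRKY18 1.03 higher (SE 0.252). JAZ10, a jasmonate repressor gene, was higher by 2.77 (SE 0.416), 1 of 3 jasmonate genes, HSP90.1 by 2.36 (SE 0.548), 1 of 10 heat shock genes, and LTI30 and ABI1 by 1.81 (SE 0.471) and 0.96 (SE 0.278), 2 of 10 dehydration genes. Over the list alone 2, 3 and 2 of these lists' genes were higher, and with the block 2, 3 and 4. The touch (adjusted p = 0.00265), heat shock (adjusted p = 0.00895), dehydration (adjusted p = 0.00895) and jasmonate (adjusted p = 0.0232) lists passed camera. None did with an estimated correlation, at adjusted p = 0.241, 0.241, 0.184 and 0.241. The root hair list had a median of -0.84 over 12 genes (adjusted p = 0.161), with 1 member, the proton pump gene HA7, higher by 1.09 (SE 0.292) and none lower, and with the block 1 was higher and 4 were lower. The mitotic cyclin gene CYCB1;1 differed by -0.93 (SE 0.227), 1 of 2 measured cell cycle genes (2 over the list alone and 2 with the block). The morning and evening clock lists had medians of 0.18 and 0.04 with no member past the threshold, and the shoot photosynthesis list, which would mark leaf tissue, had a median of -0.08 over 8 genes with none past it. With the block 1 morning clock gene was higher and 1 shoot photosynthesis gene lower.

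At 6 h 2196 probe sets differed by limma, 902 higher and 1294 lower in minus Pi roots, and 5117 did with the experiment as a block (2125 higher, 2992 lower). Of the 2196, 531 changed at least 2-fold and 2189 had one sign in 3 of 3 experiments. The count was 1200 with only the 6 arrays compared, 1438 without the 2 arrays with a second scan, 1456 and 1252 without the plus Pi and the minus Pi array of experiment 1, and 1049 without the plus Pi array of experiment 2. Without experiments 1, 2 and 3 it was 841, 232 and 1709.

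**Figure D1:**
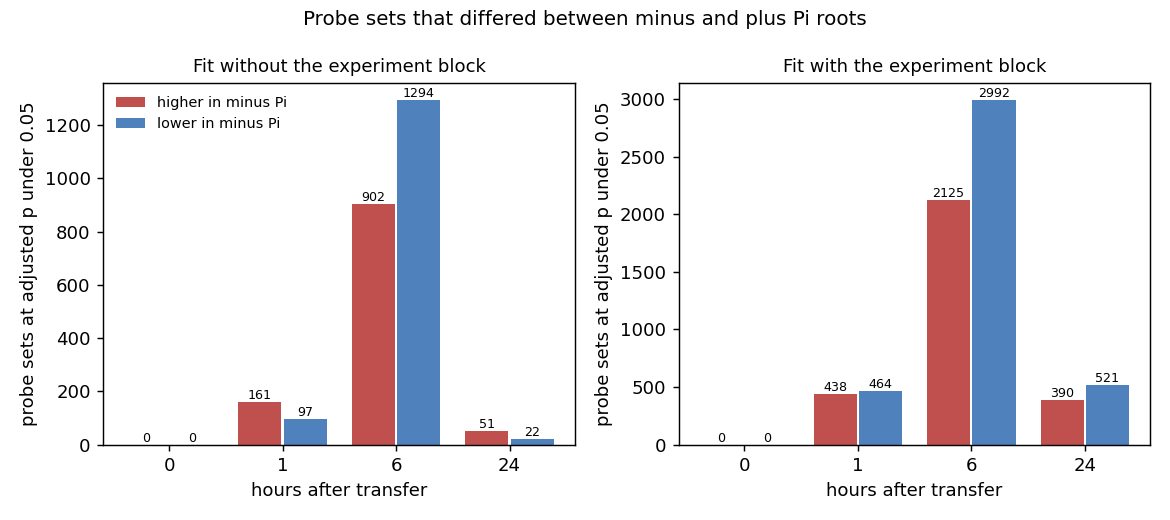
Number of probe sets (y axis, scaled separately in each panel) higher (red) or lower (blue) in minus Pi than in plus Pi roots at each time after transfer (x axis, hours), at a limma adjusted p under 0.05, without (left) and with (right) the experiment as a block. Of the 4 times, 6 h had the highest counts in both panels, 902 and 1294 without the block.

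At 24 h, OCT1 (AT1G73220), an organic cation transporter gene, was 4.18 higher without Pi (SE 0.537, adjusted p = 0.000751), or 18.1-fold. SPX1 was 3.17 higher (SE 0.357, adjusted p = 0.000302), or 8.98-fold, at 10.02 ± 0.118 against 6.85 ± 0.187 in plus Pi roots (SD, n = 3; limma). The cysteine endopeptidase gene CEP1 was higher by 2.95 (SE 0.394), the expansin-like gene EXLB1 by 2.08 (SE 0.371), JRG21 by 2.03 (SE 0.299), the transcription factor gene MYB78 by 1.78 (SE 0.217), the peroxidase gene PA2 by 1.66 (SE 0.319), BGLU25 by 1.59 (SE 0.268) and NYC1, a chlorophyll b reductase gene, by 1.55 (SE 0.281). AT2G04460, AT1G74010 and AT5G20790 were higher by 1.95, 1.88 and 1.57. Among the genes that were lower, CER4, a fatty acyl reductase gene, differed by -1.44 (SE 0.284), AT3G01190 differed by -1.35 (SE 0.225), AGP14 differed by -1.04 (SE 0.21) and the xylan gene IRX15-L differed by -0.81 (SE 0.164). AT1G33900, AT5G59680, AT3G62780, AT1G33870, AT2G21045, AT1G66930, AT1G72200 and AT2G32430 differed by between -1.37 and -0.71. The rule that chose these genes required the same sign in 3 of 3 experiments.

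Of 14 phosphate sensing and transport genes SPX1 was higher at 24 h, and over the list alone 3 were higher and 1 lower, and with the block 4 and 1. The list median was 0.28 (camera adjusted p = 0.000347; adjusted p = 0.0482 with an estimated correlation). Of 6 membrane lipid genes SQD1, which encodes an enzyme of sulfolipid synthesis, was higher by 0.94 (SE 0.121, adjusted p = 0.000751). That list had a median of 0.26 and passed at adjusted p = 0.00102, at adjusted p = 0.0482 with an estimated correlation, and not with that correlation and the block (adjusted p = 0.142). None of 13 iron acquisition genes passed over all probe sets, 3 were lower over the list alone and 2 with the block. IRT1 differed by -3.82 (SE 1.08, adjusted p = 0.171), by -3.23, -4.12 and -4.12 in the 3 experiments, and passed with the experiment as a block (adjusted p = 0.0186). FER1 differed by 0.68 (SE 0.317, adjusted p = 0.546). Median and mean differed in sign for the phosphate scavenging list (-0.09 and 0.17, 1 gene higher over the list alone and 2 with the block, adjusted p = 0.455), the glycolytic bypass list (-0.03 and 0.17, 1 gene lower over the list alone and 1 with the block, adjusted p = 0.481) and the nitrate and ammonium list (-0.16 and 0.10, adjusted p = 0.394).

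The low oxygen list had a median of 1.28 at 24 h over 8 genes, with none past the threshold over all probe sets and 4 higher over the list alone (camera adjusted p = 2.93e-06; adjusted p = 0.127 with an estimated correlation). Its medians in the 3 experiments were 1.94, 0.79 and 0.82. The xylem list had a median of -0.61 over 5 genes, with 2 lower over the list alone (adjusted p = 0.000495; adjusted p = 0.117 with an estimated correlation). The root hair list had a median of -0.83 over 12 genes, none past the threshold (adjusted p = 0.000297; adjusted p = 0.18 with an estimated correlation), and medians of -0.56, -1.55 and -0.42 in the 3 experiments. The iron acquisition (adjusted p = 0.0067), dehydration (adjusted p = 0.00696), iron storage (adjusted p = 0.0176) and touch (adjusted p = 0.0176) lists also passed. With an estimated correlation they gave adjusted p = 0.469, 0.117, 0.117 and 0.452. With the block 2 root hair genes, 1 xylem gene and 1 endodermis gene were lower, and 1 touch gene and 1 dehydration gene were higher. Of the lists of other root cell types, the endodermis list had a median of -0.06 over 4 genes, 1 lower over the list alone (adjusted p = 0.247), and the only measured phloem gene, PP2-A1, differed by 0.55 (SE 0.173, adjusted p = 0.251), a call over the list alone.

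At 24 h 73 probe sets differed by limma, 51 higher and 22 lower in minus Pi roots, and 911 did (390 higher, 521 lower) with the experiment as a block. The count was 42 at 2-fold or more, 5 with only the 6 arrays compared, 43 without the dimmest probe sets and 39 without the 3 arrays numbered out of run. It was 43 and 30 without the plus Pi arrays of experiments 1 and 2, 39 and 37 without the minus Pi arrays of experiments 2 and 3, and 76, 2 and 6 without experiments 1, 2 and 3.

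**Figure D2:**
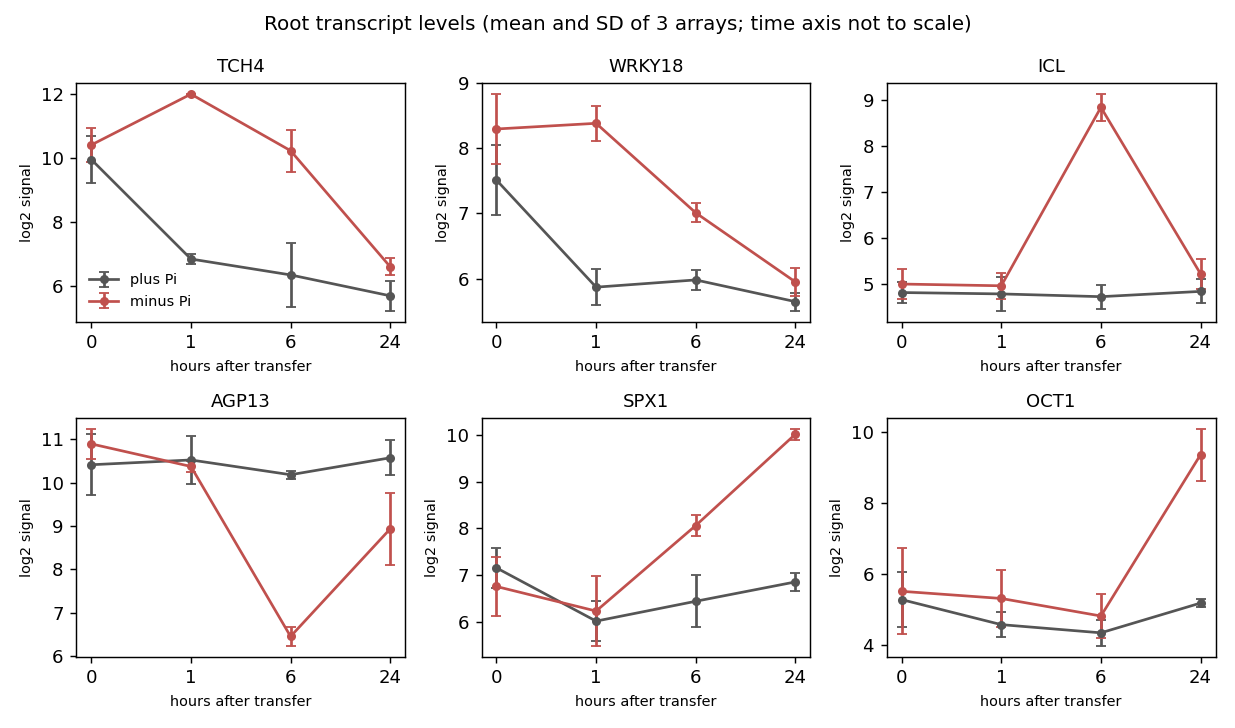
Mean log2 signal (y axis, scaled separately in each panel) of 6 named genes at 0, 1, 6 and 24 h after transfer (x axis, not to scale) in plus Pi (grey) and minus Pi (red) roots, with bars for the SD of 3 arrays. TCH4 stood at 11.99 in minus Pi and 6.83 in plus Pi roots at 1 h, and SPX1 at 10.02 and 6.85 at 24 h.

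Whether the Pi effect itself differed between times was tested as an interaction. TCH4 had a Pi effect 4.70 larger at 1 h than at 0 h (SE 0.617, limma adjusted p = 0.00601). The effect on ICL was 3.93 larger at 6 h than at 0 h (SE 0.328, adjusted p = 3.21e-06) and that on AGP13 was -4.19 relative to 0 h (SE 0.521, adjusted p = 0.000743). SPX1 had an effect 3.57 larger at 24 h than at 0 h (SE 0.506, adjusted p = 0.00982). From 6 h to 24 h the effect on ICL changed by -3.74 (SE 0.328, adjusted p = 7.34e-06). The counts were 23 probe sets at 1 h against 0 h, 426 at 6 h against 0 h, 29 at 24 h against 0 h and 59 at 24 h against 6 h, and 93, 2640, 440 and 735 with the experiment as a block. Of the 59, 8 had a higher and 51 a lower effect at 24 h, and 20 and 60 did after quantile normalization. With the block the larger part turned, to 430 with a higher and 305 with a lower effect at 24 h. Without experiment 2 the 4 counts were 0, 5, 0 and 4. The first 3 share the 0 h arrays.

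The time effect in plus Pi roots was the change without Pi withdrawal, at other hours of the day for 1 h and 6 h and at the same hour for 24 h. TCH4 fell by 3.11 (SE 0.436) at 1 h, and changed by -3.61 at 6 h and -4.26 at 24 h. It had the same sign in 3 of 3 experiments each time, as the rule for the largest changes required. At 1 h DIC2 fell by 3.30 (SE 0.342), AT4G27654 changed by -3.46 (SE 0.315), AT4G27652 by -2.98 (SE 0.346) and AT1G47400 by -2.91 (SE 0.595). EBF2, which acts in ethylene signalling, rose by 2.16 (SE 0.301) and ERS1 by 0.76 (SE 0.16), 2 of 9 ethylene genes. AT5G19110, AT5G01210, AT1G30820 and AT3G62010 rose by 1.20 to 1.99. The ethylene list passed at 1 h (adjusted p = 0.00432; adjusted p = 0.0442 with an estimated correlation, and adjusted p = 0.313 with that correlation and the block).

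Of 12 touch and rapid stress genes, 4 fell at 1 h, 5 at 6 h and 8 at 24 h in plus Pi roots (11, 8 and 11 over the list alone; 7 at 1 h with the block), with medians of -1.56, -1.36 and -1.93. These 3 comparisons share the 0 h arrays. Examples were TCH2, which changed by -1.92 at 1 h and -2.31 at 6 h (SE 0.179), and WRKY18, by -1.64, -1.53 and -1.86 at the 3 times (SE 0.252). With an estimated correlation the list passed each time, at adjusted p = 0.000299, 0.00517 and 2.52e-05. With the block added the value at 6 h was adjusted p = 0.0537. At 24 h STZ and RHL41, zinc finger genes of that list, changed by -3.37 (SE 0.53) and -2.30 (SE 0.456), and DREB2A, 1 of 10 heat shock genes, fell by 2.23 (SE 0.32).

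Clock genes changed at 6 h in plus Pi roots. AT3G54500 fell by 4.27 (SE 0.349, adjusted p = 9.29e-07), AT5G64170 fell by 1.93 (SE 0.167) and RVE1 fell by 1.36 (SE 0.161), 3 of 6 morning clock genes (4 over the list alone; list adjusted p = 1.62e-09, and adjusted p = 0.00193 with an estimated correlation). The evening genes TOC1 and PRR5 rose by 1.18 (SE 0.172) and 1.48 (SE 0.377), 2 of 5 measured (5 over the list alone and 4 with the block; adjusted p = 6.19e-07, adjusted p = 0.0493 with an estimated correlation, and adjusted p = 0.0612 with the block added). No clock gene passed at 24 h, when TOC1 differed by -0.05 (SE 0.172, adjusted p = 1). ATSDI1 and SULTR4;1 changed by -2.60 (SE 0.648) and -0.99 (SE 0.173) at 6 h, 2 of 8 sulfate genes (4 over the list alone; adjusted p = 1.6e-05, adjusted p = 0.0365 with an estimated correlation, and adjusted p = 0.105 with the block added). PYE fell by 0.70 (SE 0.143), 1 of 13 iron acquisition genes, and F3H fell by 2.46 (SE 0.603), 1 of 10 anthocyanin genes. LHCA1, a light-harvesting gene, rose by 1.40 (SE 0.277), 1 of 8 shoot photosynthesis genes (3 over the list alone), XTH26 by 2.02 (SE 0.512), 1 of 12 root hair genes, LBD38 by 1.15 (SE 0.265), 1 of 11 nitrate and ammonium genes, EBF2 by 1.29, and PP2-A1 by 0.77 (SE 0.173). BT2 and PDF2.1 rose by 2.79 (SE 0.484) and 3.37 (SE 0.687), and AT5G62360, AT5G24490 and AT4G33980 by 3.76, 2.63 and 2.52. AT4G29780 fell by 3.86 (SE 0.277) and ABCI21 fell by 3.49 (SE 0.42).

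At 24 h in plus Pi roots the transcription factor gene MYB4 rose by 0.90 (SE 0.151), the cytokinin response gene ARR6 by 1.08 (SE 0.226) and AT2G23440 by 1.1 (SE 0.225). Several further lists passed camera over time, but not with an estimated correlation. At 1 h these were the sulfate, root hair and iron acquisition lists (each adjusted p = 0.000166; adjusted p = 0.069, 0.255 and 0.371 with an estimated correlation), the low oxygen list (adjusted p = 0.00269; 0.393) and the morning clock list (adjusted p = 0.034; 0.255; adjusted p = 0.0661 with the block and the preset correlation). At 6 h they were iron acquisition (adjusted p = 2.82e-05; 0.288), shoot photosynthesis (adjusted p = 0.00448; 0.245) and root hair (adjusted p = 0.0118; 0.478). At 24 h they were heat shock (adjusted p = 0.00828; 0.323), iron acquisition (adjusted p = 0.0135; 0.586) and root hair (adjusted p = 0.0135; 0.547). Median and mean differed in sign, with no call by camera, for the phosphate sensing, nitrate, heat shock and glycolytic lists at 1 h, the ethylene list at 6 h, and the ethylene and glycolytic lists at 24 h.

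The experiment as a block moved these further list results in plus Pi roots. At 1 h it called 1 iron acquisition gene lower, and 1 nitrate and ammonium gene, 1 jasmonate gene and 2 dehydration genes higher, where none had passed without it. At 6 h it called 3 iron acquisition genes lower (1 without it), 2 nitrate and ammonium, 2 root hair and 2 shoot photosynthesis genes higher (1 each without it), 1 phosphate sensing gene higher and 1 lower, and 1 glycolytic, 1 jasmonate and 1 dehydration gene lower (none without it). At 24 h it called 1 ethylene and 1 jasmonate gene lower. With the block and the preset correlation the jasmonate list passed at 6 h (adjusted p = 0.0202; 0.108 without it) and at 24 h (adjusted p = 0.0499; 0.217 without it). The sulfate and dehydration lists passed at 24 h, just under the threshold (each adjusted p = 0.0499, against 0.0683 without it). Without the block, neither these 2 lists at 24 h nor the jasmonate list at 6 h or 24 h passed with an estimated correlation.

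Over time in plus Pi roots limma called 81 probe sets at 1 h (11 higher, 70 lower), 532 at 6 h (200 higher, 332 lower) and 113 at 24 h (4 higher, 109 lower), against 196, 1435 and 230 with the experiment as a block. With only the 6 arrays compared the counts were 2, 66 and 1, and without experiments 1, 2 and 3 they were 28, 1 and 26 at 1 h, 274, 78 and 271 at 6 h and 36, 15 and 102 at 24 h. Without the 0 h array of experiment 1 the counts at 1 h and 24 h were 40 and 69, and without that of experiment 2 the counts at 1 h and 6 h were 52 and 354. Without the later array of experiment 1 the 3 counts were 43, 272 and 69, and without that of experiment 2 the counts at 1 h and 6 h were 52 and 308.

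The Pi effects at 6 h and 24 h came from different arrays. Across the 22746 probe sets, which are not independent replicates, they correlated with r = 0.532 (Spearman 0.441). The 0 h difference, with no Pi withheld, correlated with the Pi effect at 24 h at r = -0.422 (Spearman -0.319), with that at 6 h at r = -0.158 (Spearman -0.162), and with that at 1 h at r = 0.0447 (Spearman 0.169). These values depended on experiment 2. Within experiments 1, 2 and 3 the 0 h difference correlated with that at 24 h at -0.0731, -0.612 and -0.0778. With that at 6 h it correlated at -0.04, -0.257 and 0.0299, and with that at 1 h at 0.31, -0.561 and 0.493. The 0 h pair of experiment 2 is weighed further below. Of the 51 probe sets higher at 24 h, 24 were also higher at 6 h, where lists of independent probe sets would share 2.02 (Fisher's exact test, two-sided p = 1.41e-20), and 11 of the 22 lower ones were also lower (1.25 by chance, p = 7.64e-09). None was called in opposite directions. Fisher's test takes probe sets as independent, and both Pi effects use the same spread per probe set from the same fit. Its p-values here therefore do not measure a shared response alone. With the block, 191 were higher and 307 lower at both times, and 6 and 3 were called in opposite directions. The Pi effects at 1 h and 6 h shared 60 higher probe sets (6.38 by chance) and 25 lower ones (5.52 by chance), while 7 were higher at 1 h and lower at 6 h and 1 the reverse. With the block they shared 176 higher and 149 lower ones, and 34 and 26 were called in opposite directions. Those at 1 h and 24 h shared 0 higher (0.361 by chance) and 2 lower ones (0.0938 by chance), with none called in opposite directions. With the block they shared 16 higher (7.51 by chance, Fisher's exact test, two-sided p = 0.0044) and 42 lower ones (10.6 by chance), and 5 and 4 were called in opposite directions.

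The authors' deposited table held fold changes, test statistics and p-values for the 4 Pi comparisons. The authors' deposited table called 0, 258, 2195 and 73 probe sets at 0, 1, 6 and 24 h at a p under 0.05, all of them also called by the refit here. The fold changes of the authors' deposited table differed from the refit by at most 5e-07. Its p-values differed from the refit's Benjamini-Hochberg adjusted p-values by at most 5.5e-08 where the control probe sets were kept in the adjustment. The deposited p-values thus match adjusted ones.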

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

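The tests of the 3 patterns weighed here were chosen after the result was seen, as was the test over every split that parts the pairs, while the other splits of the arrays were planned. With 3 arrays per group no single array was tested for being far from the others of its group. What brought the following results here is that the Pi effect differed between times in a direct test of that difference.

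Between 0 h and 1 h the Pi effect differed for 23 probe sets; the smallest adjusted p belonged to TCH4 (4.70), AT1G59660 (2.45), sks9 (3.40), AGP1 (1.20) and SDR2 (2.00), each with a larger effect at 1 h. Between 0 h and 6 h it differed for 426, led by AT2G41380 (4.58), ICL (3.93), ADC2 (2.23), AT5G07570 (1.71) and AGP13 (-4.19). Between 0 h and 24 h it differed for 29, led by ROPGEF14 (1.14), SPX1 (3.57), EPS1 (1.11), NANA (1.55) and AT1G33880 (-0.77). From 6 h to 24 h it differed for 59, led by AT2G41380 (-4.47), ICL (-3.74), AT5G07570 (-1.62), ADC2 (-1.67) and AT1G15430 (-1.03).

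Single arrays moved these counts. The 23 became 12 without either 0 h array of experiment 2 and 15 without its 1 h minus Pi array. The 426 became 148, 126 and 830 without the 0 h minus Pi array of experiments 1, 2 and 3, 144 without the 0 h plus Pi array of experiment 3, 227 without the 6 h minus Pi array of experiment 1 and 147 without the 6 h plus Pi array of experiment 2. The 29 became 3 to 17 without any of 11 of its 12 arrays: 13, 15 and 3 without the 0 h plus Pi array of experiments 1, 2 and 3, 5 and 6 without the 0 h minus Pi array of experiments 1 and 2, 14, 5 and 10 without the 24 h plus Pi arrays, and 17, 7 and 11 without the 24 h minus Pi arrays. The 59 became 37 and 30 without the 6 h plus Pi array of experiments 1 and 2, and 25 and 27 without the plus Pi and minus Pi 24 h arrays of experiment 2.

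For the 4 Pi effects and the 3 time effects the 6 arrays make 10 splits, too few for a share under 0.05. For the Pi effects the real splits called 0, 258, 2196 and 73 probe sets at 0, 1, 6 and 24 h and the highest of the others 2, 2, 0 and 0, where at 0 h all 10 splits, the real one included, called at least as many as the real one. For the time effects the real splits called 81, 532 and 113 at 1, 6 and 24 h, each the only 1 of 10 to call as many, and the highest of the others 0. The real splits at 1, 6 and 24 h of the Pi effects were likewise the only 1 of 10.

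For the differences of Pi effects 100 splits were drawn. Chance could not be excluded at 1 h against 0 h (14 of 100 splits called as many as the real 23, the highest other 146), at 6 h against 0 h (8 of 100; real 426, highest other 3300) or at 24 h against 6 h (10 of 100; real 59, highest other 2058). At 24 h against 0 h 4 of 100 splits called as many (real 29, highest other 2822). That share is under 0.05 but was not adjusted over the 4 differences. Of the other splits with as many calls, 13 of 13, 6 of 7, 8 of 9 and 2 of 3 kept or mirrored the real labels at 1 of the times compared. Such splits keep the real Pi effect of that time, so these shares cannot decide whether chance gave the counts. Of 75, 78, 78 and 78 drawn splits that regrouped both times, 0, 1, 1 and 1 called as many as the real one, in the order above. Their highest counts were 6, 1855, 849 and 2822 probe sets. At 24 h against 0 h the remaining 1 regrouped both times and called 2822. The splits that part every pair, as the real one does, number 32 for each difference. Of these, 7 at 1 h against 0 h (highest other 135), 3 at 6 h against 0 h (473), 6 at 24 h against 6 h (2042) and 1 at 24 h against 0 h (18), the real one included, called as many. The 1 of 32 at 24 h against 0 h is the smallest share these splits allow, again not adjusted over the 4 differences. Among these 32 are splits that keep or mirror the real labels at 1 time, so their shares cannot decide it either. Chance was therefore not excluded for any of the 4 differences, nor could these splits show that chance gave the counts.

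More probe sets passed for the Pi effect at 6 h (2196) than at 24 h (73). One deviating array is argued against, since the lowest count at 6 h with any 1 array left out, 1049, stood above the highest at 24 h, 91. A difference in the hour of the day between both arms is argued against, since the median Pi effect of the evening clock list at 6 h less that of the morning clock list was -0.138, against 2.36 for the change from 0 h to 6 h in plus Pi roots. With quantile normalization or median centring of the deposited values the lowest count at 6 h was 2081 and the highest at 24 h 83. These settings rescale values whose array medians were already close, so they cannot decide whether the authors' own normalization played a part. A transient response of roots to Pi withdrawal may remain as an explanation, and no test here separated it from a difference in harvest that applied to 1 arm at 6 h in every experiment.

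Of 12 touch and rapid stress genes 3 were higher in minus Pi than in plus Pi roots at 1 h (6 with the block), and the list, with a median of 1.25, passed with an estimated correlation (adjusted p = 0.0234) but not with the block added (adjusted p = 0.191). The second scan of the minus Pi array of experiment 3 is argued against, because the list medians in experiments 1 and 2, which had no second scan, were 1.42 and 1.31. From 0 h to 1 h the list median changed by -1.16, -0.249 and -0.586 in minus Pi roots of the 3 experiments and by -1.76, -1.63 and -1.18 in plus Pi roots. At 0 h the median difference between the arms was 0.57, 0.17 and 0.425. No member passed the threshold at 0 h, and the list did not pass there with an estimated correlation. The difference at 1 h may thus come in part from a smaller decline after the transfer without Pi and in part from any difference at 0 h, and these parts were not separated by a test. Whether single members such as TCH4 rose in minus Pi roots after 0 h (10.40 at 0 h, 11.99 at 1 h) was not tested, and a difference in handling between the arms stays open.

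The difference between the 0 h arrays of experiment 2, before any Pi had been withheld, ran against that experiment's later differences between minus Pi and plus Pi roots across probe sets, which are not independent replicates. The 3 arrays numbered out of run are argued against as the cause, since they sit on opposite sides of the 1 h and 24 h differences of experiment 2, which nevertheless correlated at 0.532. In experiments 1 and 3 the 1 h and 24 h differences correlated at only 0.0586 and -0.0102. Whether a lasting difference between the arms of experiment 2 entered its Pi effects was not tested. Crossed labels of the 0 h pair of experiment 2 stay open: the 0 h difference correlated with the 1, 6 and 24 h differences of that experiment at -0.561, -0.257 and -0.612, while its lowest correlation with a later difference of another experiment was -0.363. Plants that differed at the start may have given the same values, which was not tested. With the labels as given, the 0 h difference of experiment 2 correlated at 0.321 with that of experiment 3. With the 0 h difference of experiment 1 it correlated at -0.0214. Deviations from the group means were also compared within experiment 2, with its 1, 6 and 24 h arrays in order. Those of the 0 h minus Pi array correlated at 0.646, 0.454 and 0.594 with plus Pi arrays. With minus Pi arrays they correlated at 0.218, 0.0984 and 0.229. Those of the 0 h plus Pi array correlated at 0.417, 0.391 and 0.152 with plus Pi arrays and at 0.626, 0.346 and 0.51 with minus Pi arrays.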

How the results depend on the processing

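The tests with both 0 h arrays of experiment 2 left out, and with an experiment left out together with the block, were chosen after the result was seen; the other alternatives were planned. Counts are in the order 0, 1, 6 and 24 h or as named, "time" stands for the change from 0 h in plus Pi roots, and the cause of a change was not tested except where fewer arrays or probe sets entered.

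At 2-fold or more the Pi effect gave 108, 531 and 42 probe sets at 1, 6 and 24 h, time at 6 h gave 250, and the difference of Pi effects between 0 h and 6 h gave 261. With only the arrays compared the Pi effect gave 70, 1200 and 5, time gave 2, 66 and 1, and the differences gave 2 (1 h against 0 h), 81 (6 h against 0 h), 4 (24 h against 0 h) and 8 (24 h against 6 h).

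With the experiment as a fixed block the Pi effect gave 902, 5117 and 911, time gave 196, 1435 and 230, the differences gave 93, 2640, 440 and 735, and 498 probe sets were called in one direction at both 6 h and 24 h. As a random block it gave 882, 4753 and 672, then 207, 1370 and 222, then 67, 2281, 267 and 662.

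Without the 40% dimmest probe sets the Pi effect at 24 h gave 43, the differences 24 h against 0 h and 24 h against 6 h gave 16 and 37, and 23 probe sets were called in one direction at 6 h and 24 h. Without the 3 arrays numbered out of run the Pi effect gave 106 at 1 h and 39 at 24 h, time at 1 h gave 35, and the differences 1 h against 0 h, 24 h against 0 h and 24 h against 6 h gave 10, 4 and 25. Without the 2 arrays with a second scan the Pi effect at 6 h gave 1438 and the differences from 0 h gave 226 at 6 h and 16 at 24 h. Without both 0 h arrays of experiment 2 time gave 52 at 1 h and 332 at 6 h, and the differences from 0 h gave 0, 132 and 5.

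Leaving out each experiment or each array in turn, the Pi effect gave 12 to 234 at 1 h, 232 to 1895 at 6 h and 2 to 91 at 24 h. Time gave 1 to 71, 78 to 589 and 15 to 165, and the differences gave 0 to 24, 5 to 830, 0 to 26 and 4 to 74. Each lowest value came without experiment 2, and the 0 at 1 h and at 24 h against 0 h also without experiment 3. Of the 150 results for named genes 123 passed, and 27 to 89 did without an experiment.

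With the block and without experiment 1 the Pi effect at 24 h gave 253, time gave 48 at 1 h and 60 at 24 h, and the difference of 24 h from 0 h gave 18. With the block and without experiment 2 the Pi effect gave 100 at 1 h and 34 at 24 h, time gave 30 at 1 h and 42 at 24 h, and the differences gave 5 (1 h against 0 h), 2 (24 h against 0 h) and 16 (24 h against 6 h), and 68 named genes passed. With the block and without experiment 3 the Pi effect gave 3925 at 6 h and 267 at 24 h, time gave 864 at 6 h and 198 at 24 h, and the differences gave 1373 (6 h against 0 h) and 591 (24 h against 6 h).

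Median centring changed the sign of 1 named gene result, TOC1 at 0 h, and of 9 of 147 list medians, and quantile normalization of the same TOC1 result and 5 list medians, none of them past the threshold and none above 0.0658 in size before. An intensity trend and robust moderation changed no sign. These 4 alternatives moved 1 of 150 named genes and 1 of 147 list tests out of the threshold, both by quantile normalization. The block brought 1 named gene past it, IRT1 at 24 h, and in the list tests 4 past it and 1 out; it changed no other call of a named gene or of a list with the preset correlation. Of the named genes, 32 no longer passed without the arrays numbered out of run, 11 without those with a second scan and 17 without both 0 h arrays of experiment 2. Leaving out single experiments or arrays took named genes out of the threshold in 412 cases, brought them past it in 2 and did neither in 1506, and for the lists these were 69, 42 and 1211. Of the list tests 40 of 147 passed with the preset correlation, 12 with an estimated correlation and 18 with fry. The iron acquisition list at 0 h changed its sign without experiment 2, to a median of 0.0391, and with single arrays or experiments left out lay between -0.471 and that value. The floors of 16, 32 and 64 moved no Pi count by over 1.5 times (2195, 2008 and 1719 at 6 h), and probe-level background is not given in the sources used here, so which low signals lay at background was not tested. The alternatives not named for a count left it within 1.5 times.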

Other observations

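The tests of time against Pi effects and of the starvation genes and families under other scalings were chosen after the result was seen; the other tests of the sugar starvation genes and of the gene families were written down before.

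The differences of ICL, ASN1 and PPDK at 6 h prompted a list of sugar starvation genes, chosen after those values were seen and without these 3 genes, to ask whether minus Pi roots may have run short of carbon. All 12 measured members were higher in minus Pi than in plus Pi roots in their estimates, 2 of them past the threshold (the glutamate dehydrogenase genes GDH1 by 1.06 and GDH2 by 1.89), with a median of 0.881 (0.855 with quantile normalization, 0.903 with median centring), and the list passed camera with the preset correlation (p = 3.91e-05) but not with an estimated correlation (p = 0.132; adjusted p = 0.528 over the 4 Pi effects). At 0 h, before Pi was withheld, 9 of the 12 had a positive estimate (median 0.377). At 1 h 6 did (median -0.0159) and at 24 h 9 did (median 0.297), with none past the threshold at these 3 times. Whether the difference at 6 h exceeded that at 0 h was not tested. Camera with the preset correlation gave p = 0.00457 at 0 h, and with an estimated correlation p = 0.29 (adjusted p = 0.58 over the 4 Pi effects). The bound written beforehand, a p above 0.05, was wrong as grounds for excluding the explanation, because 12 of 12 members had the sign it needs, so it stays open.

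Whether whole gene families may have moved together was tested on 49 families with at least 10 measured members, and 0 of 147 tests passed camera with an estimated correlation. At 6 h, 8 of 15 arabinogalactan protein genes were lower in minus Pi roots (median -0.897; adjusted p = 0.625 with an estimated correlation, 3.04e-08 with the preset one), 3 of 12 EXPA expansin genes were lower, 7 of 29 NAC genes were higher, and of 28 WRKY genes 5 were higher and 1 lower. With quantile normalization and with median centring these counts at 6 h were the same, with arabinogalactan protein medians of -0.936 and -0.875. Over all 22746 probe sets, 902 were higher and 1294 lower at 6 h without these scalings. At 1 h the UBP family had a median of -0.182 (adjusted p = 0.456 with an estimated correlation, 0.000603 with the preset one), and of -0.151 and -0.121 with these scalings. The bound written beforehand, no family past the threshold, was met. A family that does not pass can still have moved together, so this bound cannot exclude shared movement, which stays open. The arabinogalactan protein family had the smallest p of the 147 tests with the preset correlation. Picked from these same tests, it does not decide the question.

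Across probe sets, which are not independent replicates, the change in plus Pi roots at 24 h and the Pi effect at 1 h correlated with r = -0.555 (Spearman -0.374).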
